A study of Homo sapiens with 20 samples.

How the data were processed

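RNA was measured in KGN cells, an established human granulosa-like tumor cell line, after 48 h in culture with vehicle (DMSO) or with a color developer of thermal paper studied beside bisphenol S. The developers were TGSA, D-8 and PF-201, and each dose was 30 µM. Each of the 4 groups held 5 libraries, 20 in all. Per the labels' protocols, the libraries were made from poly(A) RNA with a strand-marking kit. Nothing in the labels says whether the 5 libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

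Per the submitters' processing notes, reads were processed with fastp, HISAT2 2.0.5 and featureCounts 1.5.0-p3 on the GRCh38 (hg38) build, and DESeq2 1.20.0 was used. The role of each tool, the gene annotation and the strand setting of the counting are not given in the sources used here. The authors deposited 3 tables, each with 10 libraries: the counts per gene of the 5 libraries of a chemical and of the 5 DMSO libraries. The same deposited tables hold the authors' log2 fold changes, p-values and adjusted p-values for that chemical against DMSO, and the start, end and length of each gene. The counts are whole numbers of reads per gene, not normalized by the authors, per the file headers and the values. The DMSO counts were identical in the 3 tables (0 differing values), so the 20 libraries were joined to 1 matrix of counts. The tables listed 24647, 24856 and 24976 genes for TGSA, D-8 and PF-201 and 27050 in their union. The lowest row total in any table was 2, and a gene absent from a table (at most 2403) was set to 0 there. A spreadsheet had turned 24 gene symbols into dates, and these genes were kept under their identifiers. No per-sample column was left without a sample.

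The total count was 12.31 M to 29.69 M per library. A count of 0 allows up to 3 counts in a library, and this limit covers counting error only. Replicates of a group differed by more than sampling noise in every pair (chi-square per gene 3.25 to 24.9 over genes with at least 20 counts in the pair, where sampling noise alone gives a value near 1), so no library was treated as a duplicate.

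Genes were filtered with filterByExpr of edgeR 4.0.16 by group, which left 14203, and scaled by TMM. Dispersion and fold changes were fitted with edgeR's quasi-likelihood model to all 20 libraries, with a term per group and no block. The 6 contrasts were tested two-sided with Benjamini-Hochberg adjustment over the 14203 genes and a threshold of 0.05. Fold changes are log2 values with standard errors (SE) from this fit, and intervals at 95% are from its t distribution. CPM values are counts scaled to a common library total after TMM scaling, given as mean ± SD with n = 5. R 4.3.3, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.

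The design, the alternatives, the rule for named genes and 35 gene lists with 575 entries were written down before the data were examined. Of the entries, 489 were tested. For each list and contrast the members past the threshold were counted, adjusted over all genes and adjusted over the list alone. The 32 lists with at least 4 tested members were also tested with camera of limma on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast. Each list test was repeated with an estimated correlation, which allows for genes of a list varying together, and with fry. Epithelial, immune and blood, and endothelial markers had under 4 tested members and were counted without a test.

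Named genes followed a rule. Against DMSO these were the 6 highest and 6 lowest fold changes among protein-coding genes past the threshold, with a mean CPM of at least 1 and non-overlapping libraries. To these came the 3 members with the smallest p from each of the 6 lists with the largest share of members past the threshold, where at least 3 members had passed. Another 11 genes were named whatever their result, of which 7 were tested. The results of 2 of these are not reported here. Between chemicals the rule took 4 genes at each end. In all it named 68 genes, and genes named outside it are said to have been chosen after their values were seen.

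Multigene families and genes with near-identical copies are uncertain, since counting may split or drop their reads. Among the named genes these are metallothioneins, PSG1, CBS, CST1, OR2T33 and ribosomal protein genes. Genes that overlap another gene on the opposite strand are uncertain as well, because the strand setting is not given.

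The fit was tested on simulated counts drawn from the means, library sizes and dispersions of the 20 libraries, with 200 genes changed. In the step for TGSA against DMSO, which kept 13962 genes, 30% of genes changed 1.25-fold were recovered, 72% at 1.5-fold, 82% at 2-fold and 98% at 4-fold. The shares for D-8 were 24%, 70%, 82% and 94% over 13956 genes, and those for PF-201 were 34%, 72%, 82% and 94% over 13958 genes. False calls were 11 of 158, 5 of 146 and 12 of 156 calls for TGSA, D-8 and PF-201, against a nominal 5%. A list of 20 genes raised 1.25-fold passed the list test in each of the 3 simulations, and 0 of 50 random lists did. The simulated genes varied independently, so this does not show how often lists of genes that vary together pass by chance.

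Alternatives were DESeq2 size factors or upper quartile scaling in edgeR, the DESeq2 Wald test, limma-voom, no filter, a mean of at least 50 counts, the replicate number as a block, a fit of the 10 libraries of a contrast alone, a stricter threshold of 0.01, a fold above 2, and leaving out each replicate in turn. A fit without TGSA replicate 1 and D-8 replicate 1, and an exact permutation of list means, were chosen after seeing the data. A planned change of pseudocount was not run, because it was meant for normalized values and the tables hold counts. For comparisons that share the DMSO libraries, 20 simulations of unchanged groups were run and the controls were split into 2 and 3 libraries in 20 ways.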

Results

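Transcript levels were compared in KGN cells, a granulosa-like ovarian tumor line, after 48 h with vehicle (DMSO), TGSA, D-8 or PF-201, each chemical at 30 µM and each group with 5 libraries. The total count averaged 15.7 M ± 3.08 (SD, n = 5) per library with DMSO, 18.2 M ± 2.66 with TGSA, 19.9 M ± 5.52 with D-8 and 15.6 M ± 1.24 with PF-201. Mitochondrial transcripts took 1.03% to 1.49% of the counts of a library. The first principal component of log2 CPM held 36.4% of the variance and set TGSA (mean score 26.1 ± 10.2, SD, n = 5) and D-8 (30.3 ± 7.3) apart from DMSO (-29.3 ± 1.1) and PF-201 (-27.1 ± 2.5). The second component held 12.5% and set TGSA (24.6 ± 2.8) apart from D-8 (-22.4 ± 4.2), with DMSO (-1.1 ± 3.4) and PF-201 (-1.2 ± 2.5) between them. TGSA replicate 1 and D-8 replicate 1 lay nearest to DMSO of their groups, at 11.95 and 18.89 on the first component against means of 29.6 and 33.2 for the other 4 libraries.

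**Figure D1:**
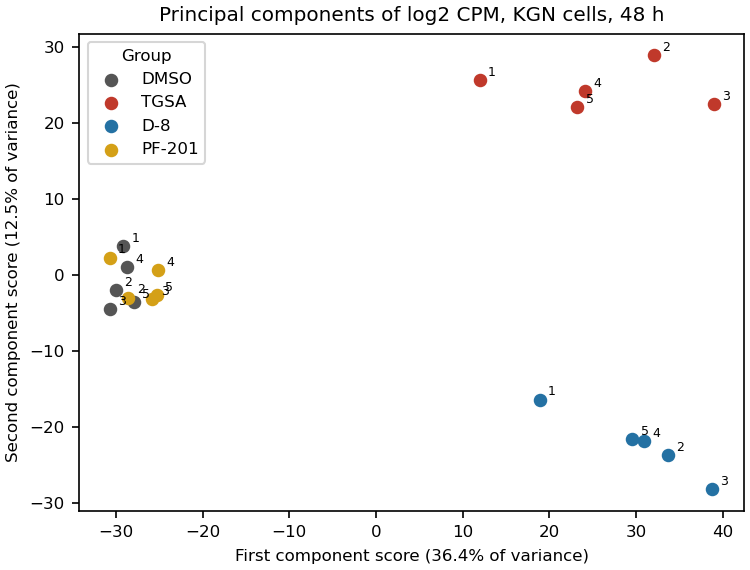
First and second principal component scores of log2 CPM (36.4% and 12.5% of the variance) for the 20 libraries, each point a library with its replicate number and colored by group. The 5 TGSA and 5 D-8 libraries lie to the right of DMSO and PF-201 on the first axis and apart on the second (mean scores 24.6 and -22.4).

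With TGSA, transcripts of glycolysis and of hypoxia-inducible genes were lower: 17 of 19 tested list members fell and 1 rose, and the same counts were found when adjusted over the list alone (median log2 fold change -1.02). PFKFB3 (chromosome 10, 6144934 to 6254644, GRCh38), which encodes an enzyme that drives glycolytic flux, fell from 162 ± 4.39 to 58.2 ± 6.89 CPM (mean ± SD, n = 5), a log2 fold change of -1.47 ± 0.07 (SE; edgeR QL, Benjamini-Hochberg adjusted p = 3.18e-16). LDHA, lactate dehydrogenase A, fell from 3658 ± 206 to 1506 ± 129 CPM (log2 fold change -1.28 ± 0.08, adjusted p = 1.72e-13). Cell-cycle transcripts were lower as well, with 22 of 22 mitosis genes and 20 of 22 DNA replication genes falling (22 and 21 adjusted over the list alone, medians -0.70 and -0.68). Inflammatory transcripts were higher, with 13 of 15 genes of NF-kappaB and cytokines rising (14 adjusted over the list alone).

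In all, 3171 genes rose and 3063 fell with TGSA of 14203 tested, 43.9%, and 336 of those that rose and 536 of those that fell exceeded 2-fold. The 5 TGSA libraries lay wholly above or below the 5 DMSO libraries for 30.3% of genes, against a chance share of 0.794%. Without TGSA replicate 1 and D-8 replicate 1, a fit chosen after seeing the data, 3239 genes rose and 3118 fell. Among the genes at the upper end by the rule, IL6 (chromosome 7, 22725884 to 22732002), a cytokine gene, rose from 2.15 ± 0.345 to 17.6 ± 4.3 CPM (log2 fold change 3.04 ± 0.21, edgeR QL adjusted p = 8.68e-13). The sialyltransferase gene ST6GALNAC5 rose by 3.59 ± 0.23 on the log2 scale, the cation channel gene TRPC6 by 3.18 ± 0.29, WIPF3 by 2.89 ± 0.26 and the nuclear receptor gene NR4A3 by 2.77 ± 0.47 (adjusted p from 8.33e-14 to 1.76e-05). NCALD, a neuronal calcium sensor gene, had the highest fold change (4.72 ± 0.64, adjusted p = 4.48e-07), but its DMSO level of 0.0754 ± 0.0545 CPM lay below the 3 counts that a 0 allows, so this fold is imprecise. At the lower end, LFNG, which encodes a modifier of Notch receptors, fell by 2.74 ± 0.14, SH3TC2 fell by 2.62 ± 0.19, COL17A1 fell by 2.53 ± 0.25 and the sterol isomerase gene EBP fell by 2.51 ± 0.32 (adjusted p from 4.66e-16 to 1.33e-07). PLAT, the tissue plasminogen activator, fell from 276 ± 25 to 50.5 ± 6.39 CPM (-2.45 ± 0.13, adjusted p = 2.07e-15). GPR146 had a log2 fold change of -2.99 ± 0.47 (adjusted p = 4.81e-06), and this was -4.09 without TGSA replicate 1. The other TGSA libraries held it at 0.06906 to 0.2748 CPM, around the 3 counts that a 0 allows, so both folds are imprecise. For each of these 12 genes the 5 TGSA libraries lay wholly on the stated side of the 5 DMSO libraries.

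By camera, 12 of 32 gene lists passed the threshold for TGSA, 8 upward and 4 downward, and 0 of them did with an estimated correlation. Hypoxia and glycolysis passed with adjusted p = 1.31e-11 (adjusted p = 0.146 with an estimated correlation), mitosis with 6.1e-10 (adjusted p = 0.248 with an estimated correlation) and NF-kappaB and cytokines with 3.08e-07 (adjusted p = 0.146 with an estimated correlation). The proliferation marker MKI67 fell from 128 ± 10.8 to 59 ± 14.5 CPM, and the thymidylate synthase gene TYMS fell by 0.94 ± 0.09 on the log2 scale. The neutrophil chemokine gene CXCL8 rose by 2.03 ± 0.12 and IL1B by 1.55 ± 0.12 (edgeR QL adjusted p = 1.02e-14 and 1.68e-11). Cytosolic ribosomal protein genes rose in 32 of 32 cases (32 adjusted over the list alone, median 0.33, camera adjusted p = 1.31e-11, adjusted p = 0.202 with an estimated correlation). Matrix genes rose in 14 of 20 cases and 1 fell (14 and 1 adjusted over the list alone, adjusted p = 2.7e-06, adjusted p = 0.248 with an estimated correlation). Of 21 ATF4 targets, genes of the amino acid stress response, 14 rose and 2 fell (14 and 2 adjusted over the list alone, adjusted p = 0.000547, adjusted p = 0.202 with an estimated correlation). Endoplasmic reticulum chaperones rose in 11 of 17 cases and 1 fell (12 and 1 adjusted over the list alone, adjusted p = 6.26e-05, adjusted p = 0.146 with an estimated correlation). The 4 tested genes of the metallothionein list split: MT2A fell by 0.52 ± 0.10 and MT1E fell by 0.45 ± 0.08, whereas MT1X rose by 0.97 ± 0.23 and the zinc exporter gene SLC30A1 by 0.43 ± 0.09 (adjusted p from 5.28e-05 to 0.000835).

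D-8 also lowered glycolytic and hypoxia-inducible transcripts, with 17 of 19 falling and 2 rising (17 and 2 adjusted over the list alone, median -1.16). PFKFB4, a second enzyme of that family, fell from 62.4 ± 8.77 to 8.23 ± 1.94 CPM (log2 fold change -2.90 ± 0.14, edgeR QL adjusted p = 1.23e-15), and the mitophagy gene BNIP3 fell from 452 ± 29.4 to 117 ± 16.1 CPM (-1.95 ± 0.10, adjusted p = 1.39e-15). Metallothioneins, which bind zinc and other metals, were higher: MT2A (chromosome 16, 56608199 to 56609497) rose from 783 ± 102 to 1653 ± 296 CPM (1.08 ± 0.10, adjusted p = 3.14e-10). MT1E rose by 1.18 ± 0.08 and MT1X by 1.86 ± 0.22. DNA replication genes fell in 21 of 22 cases (21 adjusted over the list alone, median -1.08), with RRM2, a ribonucleotide reductase subunit, at -1.55 ± 0.17 (adjusted p = 2.34e-08). Mitosis genes fell in 12 of 22 cases (13 adjusted over the list alone, median -0.27).

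With D-8, 3470 genes rose and 3298 fell, 47.7% of 14203, and 229 and 759 of these exceeded 2-fold. The 5 libraries lay wholly apart from DMSO for 30.5% of genes (chance share 0.794%), and without both replicates 1 the counts were 3472 and 3281. PSG1, a pregnancy-specific glycoprotein gene with near-identical relatives, rose from 6.6 ± 0.872 to 35 ± 3.16 CPM (log2 fold change 2.40 ± 0.12, edgeR QL adjusted p = 1.39e-15). The stress cytokine gene GDF15 rose from 1.9 ± 0.571 to 10 ± 3.46 CPM (2.35 ± 0.25, adjusted p = 7.19e-09). IFITM10 rose by 2.53 ± 0.35, SHISA2 by 2.30 ± 0.44, IL12A by 2.26 ± 0.34 and OR2T33 by 2.16 ± 0.44, all from means under 0.7 CPM in DMSO (adjusted p from 8.26e-07 to 0.000192). RIMKLA had the lowest fold change by the rule (-3.42 ± 0.29, adjusted p = 1.27e-10), followed by GPR146 (-3.05 ± 0.47), PFKFB4, DOK3 (-2.71 ± 0.34), C2orf72 (-2.71 ± 0.23) and FAM111B (-2.62 ± 0.23). For each of these genes the 5 D-8 libraries lay wholly on the stated side of the 5 DMSO libraries. Among ATF4 targets 9 rose and 10 fell of 21 (9 and 10 adjusted over the list alone, camera adjusted p = 0.885). SLC3A2, an amino acid transporter subunit, rose by 0.82 ± 0.08, whereas VLDLR and DDIT4 fell by 1.43 ± 0.11 and fell by 1.29 ± 0.10.

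By camera 15 of 32 lists passed for D-8, 10 upward and 5 downward, and 0 did with an estimated correlation. Hypoxia and glycolysis passed with adjusted p = 4.4e-11 (adjusted p = 0.113 with an estimated correlation) and DNA replication with 6.24e-11 (adjusted p = 0.223 with an estimated correlation). NRF2 targets, genes of the antioxidant response, rose in 16 of 20 cases (16 adjusted over the list alone, median 0.59, adjusted p = 5.52e-07, adjusted p = 0.212 with an estimated correlation). Ribosomal protein genes rose in 30 of 32 cases (31 adjusted over the list alone, adjusted p = 7.28e-10, adjusted p = 0.223 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes rose in 16 of 22 cases (16 adjusted over the list alone, adjusted p = 0.000153, adjusted p = 0.252 with an estimated correlation). The 4 metallothionein list genes all rose (4 adjusted over the list alone, adjusted p = 0.000585, adjusted p = 0.113 with an estimated correlation). Genes of NF-kappaB and cytokines rose in 6 of 15 cases (6 adjusted over the list alone, adjusted p = 0.00985, adjusted p = 0.286 with an estimated correlation), among them CXCL8 (1.57 ± 0.12) and IL1B (1.75 ± 0.12). Of the 5 tested aryl hydrocarbon receptor targets 4 rose (4 adjusted over the list alone), with CYP1B1 (chromosome 2, 38066973 to 38109902), a steroid-metabolizing enzyme gene, going from 16.1 ± 1.91 to 27.4 ± 5.13 CPM (0.76 ± 0.14, edgeR QL adjusted p = 7.51e-05). This list passed narrowly (camera adjusted p = 0.0458, adjusted p = 0.223 with an estimated correlation). It was lost without DMSO replicate 3 (0.0548), D-8 replicate 1 (0.0602), D-8 replicate 2 (0.0589) or D-8 replicate 4 (0.0504). NRF2 targets also rose with TGSA, in 10 of 20 cases (camera adjusted p = 0.000547, 0.323 with an estimated correlation). So did oxidative phosphorylation genes, in 13 of 22 cases (0.00226, 0.334 with an estimated correlation). Endoplasmic reticulum chaperones also rose with D-8, in 12 of 17 cases (0.000585, 0.212 with an estimated correlation). Matrix genes rose with D-8 in 11 of 20 cases and 1 fell (0.0103, 0.417 with an estimated correlation).

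With PF-201, 0 of 14203 genes passed the threshold in the edgeR QL fit of the 20 libraries, and 1053 had an unadjusted p under 0.05, where 710 are expected by chance. The DESeq2 Wald test called 4 higher and 9 lower, limma-voom called 0, and edgeR without the filter on low counts called 41 higher and 23 lower. With the replicate number as a block, edgeR called 21 higher and 12 lower, so the count of 0 depends on the model. No label gives that number a meaning, but the own number was the best match in 32 of 60 cases, more often than chance gives. A shared day or culture therefore stays open. The 95% interval lay within 1.5-fold for 75.2% of genes and within 2-fold for 89.1%. The 5 libraries lay wholly apart from DMSO for 2.25% of genes, against a chance share of 0.794%. CYP1B1 had a lower mean than in DMSO, 9.28 ± 2.12 against 16.1 ± 1.91 CPM with all 5 libraries below (log2 fold change -0.80 ± 0.15, 95% interval -1.12 to -0.49), but did not pass (adjusted p = 0.0974). The smallest adjusted p was 0.0631, for the retinaldehyde dehydrogenase gene ALDH1A3 (-0.46), which was chosen after its values were seen.

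In the fit of the 10 PF-201 and DMSO libraries alone, 4 genes rose and 5 fell, and all 9 were named after their values were seen. CYP2S1, a cytochrome P450 gene, fell by 0.59 ± 0.07 (edgeR QL adjusted p = 0.00141), CYP1B1 fell by 0.81 ± 0.14 and ALDH1A3 fell by 0.46 ± 0.08 (both 0.0301), and NTN4 and KCTD9 fell by 0.34 and fell by 0.32 (both 0.0474). FAM20C rose by 0.37 (adjusted p = 0.0301), CDKN1A by 0.29, TMEM132A by 0.36 and PYCR1 by 0.40 (each 0.0474). In the fit of 20 libraries the adjusted p of these 9 genes ran from 0.0631 to 0.261. By camera 15 lists passed for PF-201, with 0 members past the threshold over all genes in any list. The aryl hydrocarbon receptor targets were lowest (median -0.35, adjusted p = 1.51e-05), with 4 of 5 falling when adjusted over the list alone, and this list alone passed with an estimated correlation (adjusted p = 0.0193 with an estimated correlation). It did not pass an exact permutation of list means chosen after seeing the data, in which 0 of 32 lists passed (adjusted p = 0.0847). Its p before adjustment was 0.00794, the smallest that 252 labelings allow, and a list alone cannot pass there after adjustment over 32. The 13 mitochondrially encoded mRNAs had a median of 0.18 (adjusted p = 1.51e-05, adjusted p = 0.4 with an estimated correlation) and 5 of them rose when adjusted over the list alone. Hypoxia and glycolysis, lower with both other chemicals, had a median of 0.01 (adjusted p = 0.842).

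**Figure D2:**
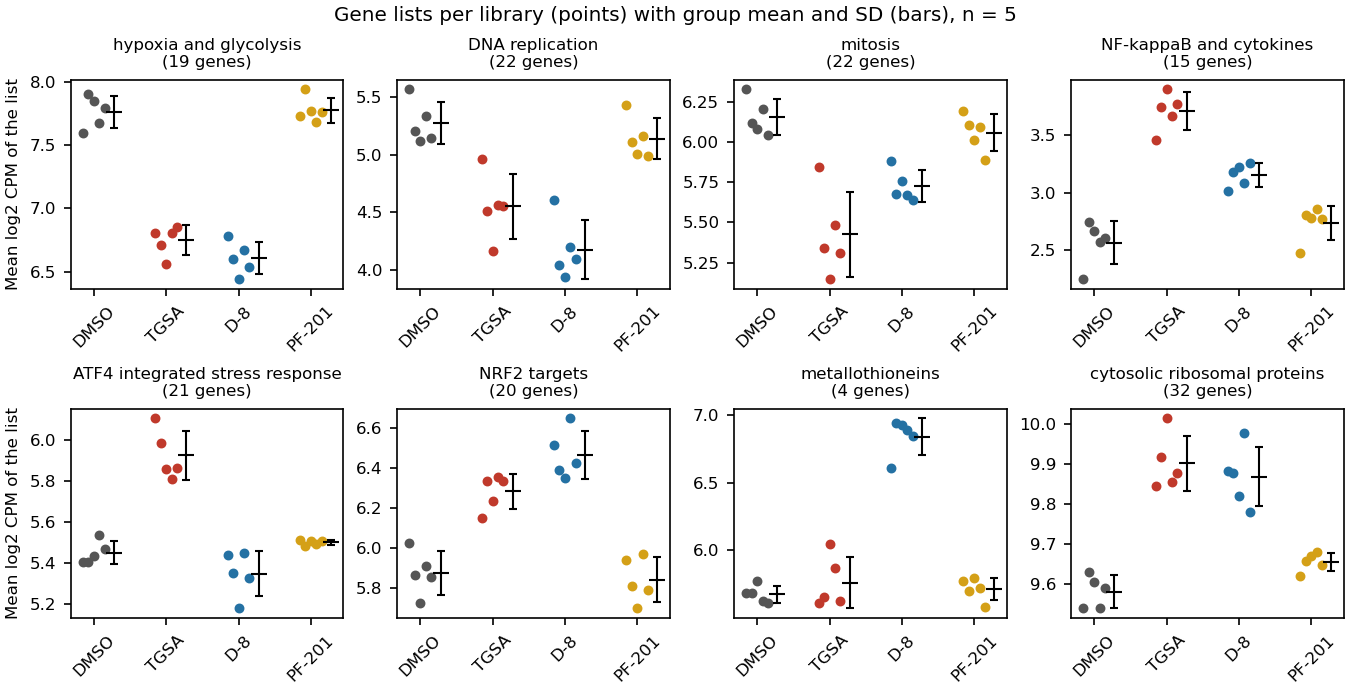
Mean log2 CPM of 8 gene lists per library (points) for DMSO, TGSA, D-8 and PF-201, with bars for group mean and SD (n = 5). Hypoxia and glycolysis lies lower with TGSA and D-8 (median log2 fold changes -1.02 and -1.16) and near DMSO with PF-201 (0.01).

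TGSA and D-8 differed from each other in 3714 genes, 1900 higher with TGSA and 1814 lower, 26.1% of 14203 (edgeR QL). EDN1 (chromosome 6, 12290363 to 12297194), which encodes the vasoconstrictor endothelin 1, went from 3.77 ± 0.603 CPM in DMSO to 8.63 ± 2.15 with TGSA and 1.23 ± 0.208 with D-8 (difference 2.81 ± 0.21 on the log2 scale, adjusted p = 6.26e-12). The transcription factor gene KLF2 (chromosome 19, 16324817 to 16327874) moved the other way, from 222 ± 43.4 to 98.4 ± 20.2 CPM with TGSA and 455 ± 135 with D-8 (-2.21 ± 0.16, adjusted p = 2.32e-12). MT2A differed by -1.60 ± 0.10 (adjusted p = 9.59e-14), having fallen with TGSA and risen with D-8. ATF4 targets were higher with TGSA in 12 of 21 cases and lower in 2 (13 and 3 adjusted over the list alone, median 0.43).

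Of the genes that differed, 265 were more than 2-fold higher with TGSA and 136 more than 2-fold lower, and the libraries of the groups lay wholly apart for 14.8% of genes (chance share 0.794%). Without both replicates 1, 1737 were higher and 1618 lower. The other genes at the upper end by the rule were NCALD (4.53 ± 0.60, 5.18 without D-8 replicate 2 or 5), CBS (2.87 ± 0.35) and CST1 (2.70 ± 0.36), and those at the lower end were FOXL1 (-2.60 ± 0.39), MYO7B (-2.52 ± 0.30) and SERPINB7 (-2.18 ± 0.22), with adjusted p from 3.59e-09 to 5.25e-06. NCALD averaged 0.0922 ± 0.126 CPM with D-8, again below the 3 counts that a 0 allows, so this fold is imprecise too. For each of these 8 genes the libraries of TGSA and D-8 were wholly apart. IL6 was higher with TGSA by 2.10 ± 0.20 (adjusted p = 8.84e-10). By camera 11 of 32 lists differed, and 2 did with an estimated correlation, metallothioneins (adjusted p = 0.000131, adjusted p = 0.0448 with an estimated correlation) and LXR targets, genes of cholesterol efflux (median -0.25, 0.00348, adjusted p = 0.0448 with an estimated correlation). ATF4 targets passed with 6.85e-05 (adjusted p = 0.0954 with an estimated correlation), and aryl hydrocarbon receptor targets, 4 of 5 lower with TGSA (4 adjusted over the list alone), with 0.00429 (adjusted p = 0.0954 with an estimated correlation). Some genes named after their values were seen changed in opposite directions: PSAT1 rose by 1.56 with TGSA and fell by 0.93 with D-8, PHGDH rose by 1.00 and fell by 0.54, and ATF4 itself rose by 0.45 and fell by 0.47, each past the threshold. This did not hold for related enzymes: PSPH did not pass with TGSA (0.11, adjusted p = 0.623) and fell by 0.42 with D-8 (adjusted p = 0.0478), SHMT2 rose by 0.77 and 0.23, and MTHFD2 rose by 1.07 and 0.64.

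For some genes no difference between the chemicals was found. The 95% interval of the difference lay within 1.5-fold for 62.5% of genes. MKI67 differed by -0.05 (interval -0.32 to 0.22, adjusted p = 0.82), LDHA by -0.12 (-0.29 to 0.05, adjusted p = 0.325), GDF15 by 0.05 (-0.38 to 0.48, adjusted p = 0.891) and RPS14 by -0.00 (-0.11 to 0.11, adjusted p = 0.989). As a set, mitosis genes were lower with TGSA than with D-8 in 12 of 22 cases and higher in 0 (15 and 0 adjusted over the list alone, camera adjusted p = 0.000131, adjusted p = 0.544 with an estimated correlation). DNA replication genes were higher with TGSA in 9 of 22 cases and lower in 1 (12 and 1 adjusted over the list alone, adjusted p = 0.0034, adjusted p = 0.667 with an estimated correlation). The exact permutation of list means, chosen after seeing the data, passed for neither (adjusted p = 0.119 and 0.159). The hypoxia and glycolysis list did not differ as a set (camera adjusted p = 0.408), with 6 of 19 members higher and 4 lower with TGSA than with D-8 (6 and 4 adjusted over the list alone). Of the 6, PFKFB4 and BNIP3 were higher by 0.72 ± 0.14 and 0.54 ± 0.10 (edgeR QL adjusted p = 0.000307 and 5.26e-05), and of the 4, all named after their values were seen, SLC2A3 differed by -0.93, ALDOA by -0.54, NDRG1 by -0.51 and SLC2A1 by -0.32 (adjusted p from 1.95e-10 to 0.00175).

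**Figure D3:**
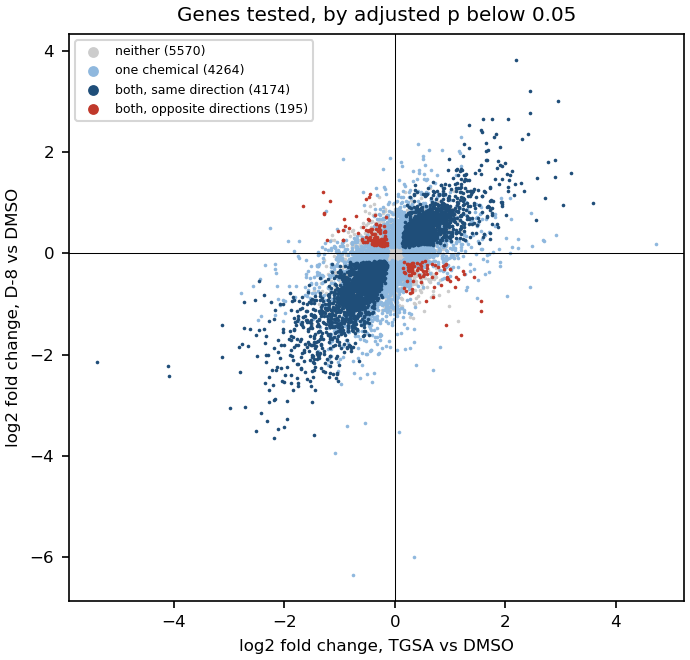
Log2 fold change against DMSO with D-8 (vertical axis) and with TGSA (horizontal axis) for the 14203 tested genes, each point a gene. Of these, 4174 passed the threshold with both chemicals in the same direction and 195 in opposite directions.

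Against DMSO, 2181 genes rose with both TGSA and D-8 and 1993 fell with both, where independent lists of these sizes would share 775 and 711. Another 84 rose with TGSA and fell with D-8, among them EDN1, and 111 went the other way, among them KLF2 and MT2A. Fold changes of chemicals that share a control are correlated by construction, so the value was set beside simulations of unchanged groups. Across genes, which are not independent replicates, r was 0.707 for TGSA and D-8, against 0.516 (0.493 to 0.532) in the simulations, and the covariance was 0.219 against 0.0191. With the DMSO libraries split so that no control was shared, r was 0.547 to 0.622 and 2730 to 2920 genes changed the same way with both. For PF-201, r was 0.274 with TGSA and 0.255 with D-8, where the simulations gave 0.507 (0.488 to 0.521) and 0.511 (0.495 to 0.532). The simulated groups held no changed genes, so their r is no baseline for a pair in which a chemical changed many genes. The covariances of PF-201, 0.0323 and 0.0313, were above the simulated 0.019 and 0.0192. With split controls the r of PF-201 was 0.00898 to 0.143 with TGSA and 0.037 to 0.123 with D-8, and the covariances were 0.00155 to 0.0188 and 0.0059 to 0.0169.

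Against PF-201 in place of DMSO, TGSA had 3049 higher and 2899 lower genes, and D-8 3312 higher and 3196 lower (edgeR QL), of which 290 and 531, and 191 and 742, exceeded 2-fold. The libraries lay wholly apart for 29% and 29.3% of genes (chance share 0.794%). PELI2, an E3 ubiquitin ligase gene, was higher with TGSA than with PF-201 by 3.09 ± 0.34 on the log2 scale, and the checkpoint receptor gene LAG3 differed by -3.10 ± 0.49, or -4.24 without TGSA replicate 1. The other TGSA libraries held LAG3 at 0.0499 to 0.2072 CPM, around the 3 counts that a 0 allows, so both LAG3 folds are imprecise. BMP6, a growth factor gene of the ovary, was higher with D-8 than with PF-201 by 2.26 ± 0.27, and EGR2 differed by -2.79 ± 0.47 (adjusted p from 1.46e-08 to 1.42e-05 for these 4 genes). The other genes at the ends were named above and went the same way as against DMSO. Hypoxia and glycolysis was lower with TGSA in 17 of 19 cases (17 adjusted over the list alone, camera adjusted p = 1.51e-11, adjusted p = 0.188 with an estimated correlation). The same held with D-8 in 17 of 19 cases (17 adjusted over the list alone, adjusted p = 1.06e-11, adjusted p = 0.0829 with an estimated correlation). Aryl hydrocarbon receptor targets were higher with D-8 than with PF-201 in 4 of 5 cases (4 adjusted over the list alone, median 0.81, adjusted p = 0.0026, adjusted p = 0.0829 with an estimated correlation), and CYP1B1 by 1.56 ± 0.15 (edgeR QL adjusted p = 1.74e-09).

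Genes of steroid synthesis and granulosa identity were named whatever their result. STAR (chromosome 8, 38143649 to 38151265), which carries cholesterol into mitochondria for steroid synthesis, went from 36 ± 3.46 CPM in DMSO to 104 ± 17.3 with TGSA (1.53 ± 0.13, edgeR QL adjusted p = 6.27e-11) and 56 ± 13.3 with D-8 (0.64 ± 0.13, adjusted p = 0.000179). With PF-201 its mean was 42.6 ± 6.9 CPM (0.25 ± 0.13, interval -0.02 to 0.52, adjusted p = 0.674). STAR was higher with TGSA than with D-8 by 0.89 ± 0.13 (adjusted p = 2.42e-06). CYP11A1, the first enzyme of the pathway, did not pass with any chemical (0.17 ± 0.11, -0.04 ± 0.11 and 0.09 ± 0.11 for TGSA, D-8 and PF-201). FOXL2, a granulosa transcription factor gene, rose by 0.40 ± 0.10 with TGSA (adjusted p = 0.00211) and did not pass with D-8 (0.15 ± 0.10, adjusted p = 0.243) or PF-201 (0.19 ± 0.10). Of 13 steroidogenesis genes 3 rose and 2 fell with TGSA and 7 rose and 2 fell with D-8 (3 and 2, and 8 and 2, adjusted over the list alone), and the list did not pass against other genes (camera adjusted p = 0.402 and 0.174). Of 12 granulosa markers 5 rose and 2 fell with TGSA and 3 rose and 1 fell with D-8 (the same counts adjusted over the list alone, camera adjusted p = 0.202 and 0.239). By the exact permutation of list means, chosen after seeing the data and not a comparison with other genes, steroidogenesis was higher with TGSA by 0.16 ± 0.03 (SE, adjusted p = 0.0141) and granulosa markers by 0.27 ± 0.07 (adjusted p = 0.0254), and with D-8 neither passed (adjusted p = 0.107 and 0.0741). STAR alone rose by 1.53 with TGSA, and the steroidogenesis mean was not tested without it (list median 0.145). INHBA, which encodes an activin and inhibin subunit and was chosen after its values were seen, rose by 2.17 with TGSA (adjusted p = 8.41e-17) and by 1.36 with D-8.

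CYP1A1 stayed at 0.388 to 0.646 CPM in the group means and did not pass in any of the 6 comparisons. The aromatase gene CYP19A1 was too low to be tested, with 5 to 17 counts per library with TGSA, 0 to 4 with DMSO, 0 to 3 with D-8 and 0 to 2 with PF-201. HSD3B2 and ESR2 had at most 5 and 6 counts in a library and were not tested either, and FSHR was not analysed here. Among markers of other cell types, 0 of 2 epithelial and 0 of 1 immune and blood markers passed with TGSA, and with D-8 1 epithelial marker, KRT7, fell (the same counts adjusted over the list alone). KRT7 was named after its values were seen. Of 4 theca and stroma markers, STAR among them, 2 rose and 1 fell with TGSA and 3 rose with D-8 (the same counts adjusted over the list alone). That list did not pass by camera (adjusted p = 0.187 and 0.104), while by the same exact permutation its mean was higher with TGSA by 0.55 ± 0.09 (adjusted p = 0.0141) and with D-8 by 0.40 ± 0.08 (adjusted p = 0.0134). STAR, which rose with both chemicals, is 1 of its 4 genes, and this mean was not tested without STAR. Of 3 endothelial markers VWF fell with TGSA and D-8 (-1.77 ± 0.26 and -1.14 ± 0.25), KDR rose with D-8 (1.10 ± 0.14) and PECAM1 fell with D-8 (-0.62 ± 0.21, adjusted p = 0.019), with the same calls adjusted over the list alone. The PECAM1 call was lost without DMSO replicate 3 (0.0616) or 5 (0.0697) and without the filter on low counts (0.0623).

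**Figure D4:**
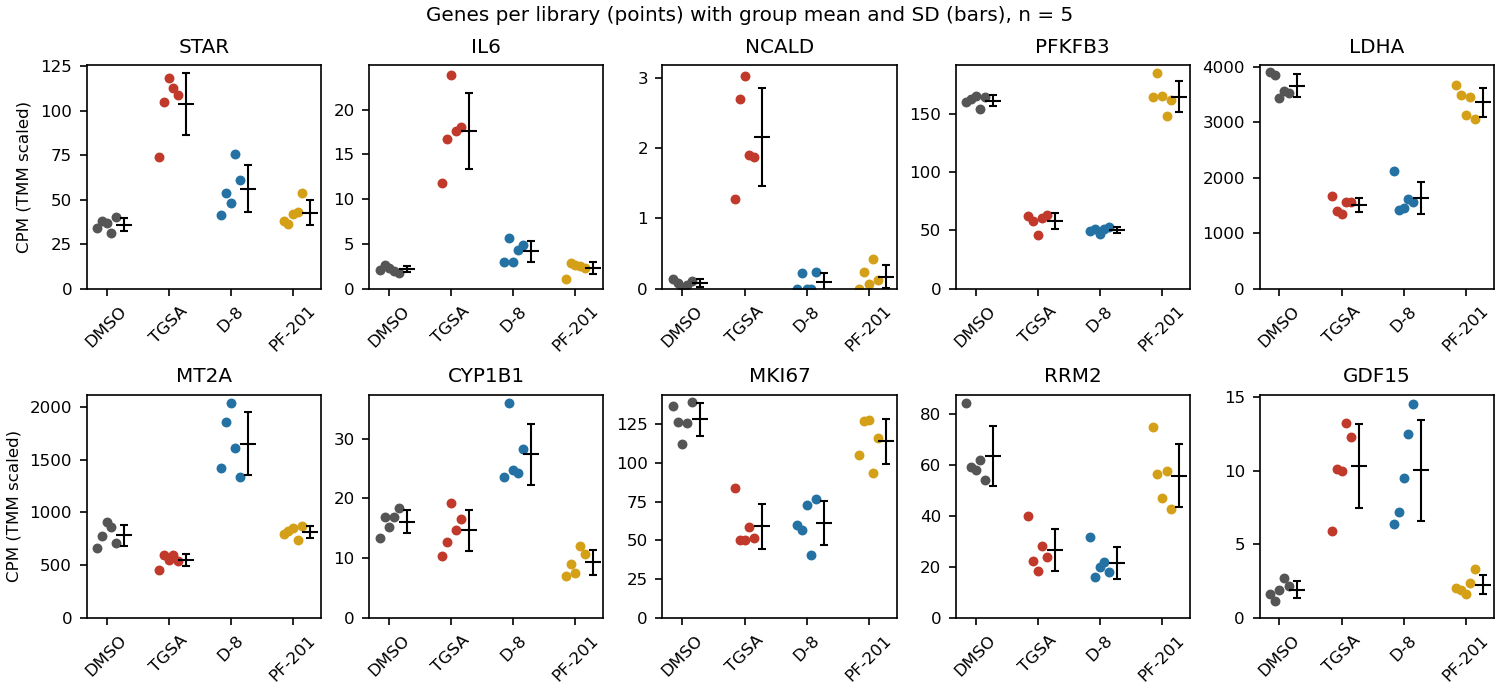
CPM after TMM scaling of 10 genes per library (points) for DMSO, TGSA, D-8 and PF-201, with bars for group mean and SD (n = 5). STAR averages 36, 104, 56 and 42.6 CPM and PFKFB3 162, 58.2, 50.4 and 165 CPM in these groups.

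In the deposited tables the authors' own adjusted p was under 0.05 for 6354 genes with TGSA, 6333 with D-8 and 130 with PF-201. Of the genes deposited as changed, 93.2% with TGSA and 95.7% with D-8 were also called here in the same direction. The 130 genes for PF-201, 80 higher and 50 lower with 0 over 2-fold, all had the same direction here, and 0 of them passed in the edgeR QL fit of 20 libraries. The deposited table for PF-201 holds 10 libraries. In the edgeR QL fit of these 10 libraries alone 9 genes passed, each of them among the 130 and in the same direction.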

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

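The tests of library depth and of vehicle RNA below were set before their results were seen, but the margin applied to the TGSA value was chosen only after it was seen.

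TGSA replicate 1 and D-8 replicate 1 lay nearest to the DMSO libraries on the first principal component, at 11.95 against a mean of 29.6 for the other 4 TGSA libraries and at 18.89 against 33.2 for the other 4 D-8 libraries. Thinning each library to the lowest total of its group closed 0.701% and 0.509% of these gaps, which argues against depth for both. Vehicle RNA in a library predicts equal shares of the DMSO profile over risen and fallen genes. In D-8 replicate 1 the shares were 0.356 and 0.179, a difference of 0.177 ± 0.025, above the bound of 0.1. The SE is from resampling genes within the library and measures no spread between libraries. The difference argues against vehicle RNA in D-8 replicate 1 only as far as genes can be treated as independent. In TGSA replicate 1 the shares were 0.325 and 0.213, and the difference of 0.113 ± 0.022 passed the bound of 0.1 by less than its SE, so vehicle RNA and a weaker response of that library cannot be told apart here. On the log scale, where a uniformly weaker response gives equal shares, they were 0.258 and 0.264 in D-8 replicate 1 and 0.227 and 0.316 in TGSA replicate 1, so a weaker response may be the cause for D-8, and culture or day stay open because no label gives them.

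A library lay far from the other 4 of its group in 19 of 304 groups of values (32 of library measures and 272 of named genes), where chance gives about 1 in 20, or 15. D-8 replicate 1 had the highest total count of its group, 29.69 M against 16.5 M to 18.45 M. The same library had the highest KIF20A (107 against 76.71 to 83.24 CPM), the highest LDHA (2126 against 1425 to 1619 CPM) and the lowest OR2T33 (0.8989 against 1.991 to 2.332 CPM) of D-8. TGSA replicate 1 had the highest MKI67 (84.13 against 50.07 to 58.78 CPM), the highest GPR146 (0.8667 against 0.06906 to 0.2748 CPM) and the highest LAG3 (0.7138 against 0.0499 to 0.2072 CPM) of TGSA. TGSA replicate 3 had the highest RPS4X (2007 against 1748 to 1812 CPM), the lowest PFKFB3 (46.37 against 58.43 to 62.99 CPM) and the lowest RIMKLA (0.4122 against 2.436 to 2.794 CPM). The FOXL1 value of TGSA replicate 3 was the same 0.4122 CPM, against 0.3453 to 0.3569 in the other TGSA libraries. DMSO replicate 1 had the lowest CENPE (30.26 against 33.97 to 35.12 CPM), the highest RRM2 (84.16 against 54.12 to 61.96 CPM) and the lowest CXCL8 (13.67 against 19.23 to 21.44 CPM) of DMSO. ST6GALNAC5 was highest in D-8 replicate 4 (4.083 against 2.213 to 2.746 CPM) and IL12A in TGSA replicate 2 (3.453 against 1.683 to 1.924 CPM). With PF-201, IFITM10 was highest in replicate 2 (1.216 against 0.4983 to 0.6628 CPM), PECAM1 in replicate 4 (4.129 against 2.652 to 2.936 CPM) and MYO7B in replicate 5 (4.484 against 2.998 to 3.417 CPM).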

How the results depend on the processing

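The fit without TGSA replicate 1 and D-8 replicate 1 and the exact permutation of list means were chosen only after the results were seen. For 654 values of named genes (450 past the threshold), 11948 of 12154 values under alternatives kept their side of the threshold. Of the others, 90 were no longer past it, 116 were newly past it and 0 reversed. For 192 list results (78 past the threshold), 2846 of 3232 values kept their side, 171 were no longer past, 214 were newly past and 1 reversed. Direction was compared only where the main value or the alternative passed the threshold, and not for fry's mixed test, which gives none. For all but stricter thresholds and smaller fits, the cause was not tested.

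Counts above and below DMSO, or in each direction, stayed within 1.5 times of the stated counts for TGSA, D-8 and the 3 comparisons between chemicals under both scalings, the DESeq2 Wald test, limma-voom, both filters, the block, the fit of 10 libraries and each library left out. A fold above 2 left 336 and 536 genes for TGSA, 229 and 759 for D-8, 265 and 136 for TGSA against D-8, 290 and 531 for TGSA against PF-201, and 191 and 742 for D-8 against PF-201, and adjusted p under 0.01 left 1206 and 1153 for TGSA against D-8, by construction. For PF-201 against DMSO (0 higher, 0 lower), the DESeq2 Wald test gave 4 and 9, no filter 41 and 23, the replicate number as a block 21 and 12, the fit of 10 libraries 4 and 5, and limma-voom, both scalings and the higher filter 0. Leaving out each library gave 2865 to 3216 higher and 2775 to 3078 lower for TGSA, 3195 to 3425 and 3032 to 3254 for D-8, 0 to 0 and 0 to 1 for PF-201 (1 without DMSO replicate 1 or PF-201 replicate 3), 1700 to 1902 and 1586 to 1800 for TGSA against D-8, 2680 to 3019 and 2579 to 2896 for TGSA against PF-201, and 3043 to 3274 and 2947 to 3133 for D-8 against PF-201.

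Lists past the threshold, in the order TGSA, D-8 and PF-201 against DMSO, TGSA against D-8, TGSA against PF-201 and D-8 against PF-201, numbered 12, 15, 15, 11, 13 and 12. With an estimated correlation they numbered 0, 0, 1, 2, 0 and 0, by fry's directional test 25, 27, 2, 16, 26 and 27, by its mixed test 29, 32, 2, 30, 30 and 30, and by exact permutation 21, 23, 0, 11, 25 and 21. Without 1 library they ran from 11 to 14, 11 to 16, 10 to 16, 10 to 11, 12 to 15 and 11 to 13. The list of fatty acid oxidation and PPAR targets with D-8 reversed: camera ranked it upward among all genes (adjusted p = 0.947), while its mean fell by 0.201, its median was -0.031, and the exact permutation was lower with adjusted p = 0.0231. The 4174 genes shared by TGSA and D-8 went down to 2730 to 2920 with split controls, those shared by TGSA and PF-201 were 0 and became 0 to 1 with split controls and 21 with the block, and those shared by D-8 and PF-201 became 21 with the block.

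The replicate numbers were not used to pair the samples, since no label gives them a meaning and 7 of 30 correlations between libraries of the same number were over 0.1 (-0.032 to 0.21, with 0.11 to 0.21 for number 1). As a hint from the data, the own number was the best match in 32 of 60 cases, where chance gives 1 in 5, so a shared day or culture stays open. The block gave 3391 and 3277 genes for TGSA and 3661 and 3530 for D-8. Under upper quartile scaling the median log2 fold change of all genes was -0.045 to -0.066 for TGSA and D-8 against DMSO or PF-201. Against DMSO it gave 2743 higher and 3486 lower genes for TGSA and 2817 and 3875 for D-8, so the balance of directions depends on the scaling. At the depth of 12.31 M to 29.69 M, genes such as CYP19A1 had counts too low to be tested.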

Other observations

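The 4 lists of the next 2 paragraphs, all tests of gene and list counts under other splits, and the test of the PF-201 spread were chosen only after the results were seen. Since these 4 lists were put together from fold changes already seen, their counts describe the genes and are no test of the lists.

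Among genes of the contractile cytoskeleton and targets of the SRF and YAP pathways, 16 of 19 rose and 0 fell with TGSA. TAGLN rose by 2.68 ± 0.24 on the log2 scale, the matrix-cell signaling gene CTGF by 1.87 ± 0.07, the myosin light chain gene MYL9 by 1.72 ± 0.07 and CALD1 by 1.70 ± 0.07 (SE, n = 5, edgeR QL adjusted p from 1.03e-18 to 1.8e-10). With D-8, 7 rose and 5 fell, and in the direct comparison 14 were higher and 1 lower with TGSA than with D-8. Enzymes of serine, glycine and one-carbon metabolism rose with TGSA in 8 of 12 cases and 1 fell. With D-8, 5 of these rose and 4 fell, and 8 were higher and 1 lower with TGSA than with D-8.

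Of 15 circadian clock and clock output genes, 9 were lower with TGSA than with D-8 and 0 were higher. DBP rose with D-8 by 1.37 ± 0.19, NR1D1 by 1.18 ± 0.13 and PER1 by 1.17 ± 0.13 (SE, n = 5, edgeR QL adjusted p from 1.7e-08 to 7.6e-07), and against DMSO 7 of the list rose and 2 fell. Splicing factors fell in 25 of 38 cases with TGSA and 4 rose, and 22 fell and 8 rose with D-8. HNRNPM fell by 1.11 ± 0.15 with TGSA and fell by 1.46 ± 0.15 with D-8.

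The lower hypoxia and glycolysis transcripts with TGSA and D-8 were weighed against technical causes. Over 3 normalizations and both chemicals the median log2 fold change nearest to 0 was -1.022, while the median of all genes ran from -0.005 to -0.062. The fall relative to other genes thus does not hang on the choice among the 3, but they cannot test a scaling error that all share. With the trend over gene length removed the list median nearest to 0 was -0.998, which argues against length bias as the whole cause. Among 14 hypoxia-inducible genes outside the list, 11 fell and 1 rose with TGSA, 11 fell and 0 rose with D-8 (medians -0.644 and -0.545), and 0 passed the threshold with PF-201. This is consistent with lower hypoxia-inducible transcription as a whole, as a hypothesis. Oxygen in the medium, cell density and protein levels were not measured, so what lowered these transcripts stays open.

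The count of 0 genes for PF-201 in the fit of 20 libraries and 9 in the fit of 10 was weighed as well. Fold changes differed between these fits by a median of 0.00118 over 13672 genes, while standard errors were larger in the fit of 20, with a median ratio of 1.13. The fitted coefficient of variation between libraries was 0.107 for TGSA and 0.13 for D-8, against 0.0892 for DMSO and 0.0868 for PF-201. It was 0.108 in the fit of 20 and 0.0895 in the fit of 10. A candidate explanation, with which these values go, is the wider spread of the TGSA and D-8 libraries in the shared estimate. The fit of 10 is not thereby the better one: 3 of its 100 splits, the real one included, gave as many as 9 genes, and another split called 507, several times the real count, which points to a structure of the samples other than treatment.

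Other splits of the 10 libraries of a comparison, 100 of them with the real one, were used to ask whether chance can be excluded. For gene counts it can for TGSA (6234 genes, highest other 2402, 1 split with as many), D-8 (6768, 2541, 1 split), TGSA against D-8 (3714, 1197, 1 split), TGSA against PF-201 (5948, 1785, 1 split) and D-8 against PF-201 (6508, 1711, 1 split). For PF-201 against DMSO the splits decide nothing, since the real count is 0 and all 100 splits reach it (highest other 46). For counts of lists the splits decide nothing for TGSA (12 lists, highest other 14, 12 splits with as many), D-8 (15, 16, 7 splits), TGSA against PF-201 (13, 14, 11 splits) and D-8 against PF-201 (12, 15, 8 splits). Splits that exchange only some libraries keep part of the difference between the groups, and camera ranks a list against other genes. Fewer splits reached the real count for TGSA against D-8 (11 lists, highest other 11, 3 splits) and for PF-201 (15, 14, 1 split). Other splits of TGSA and D-8 tied the real count, and the margin for PF-201 was narrow. These counts were not adjusted over the 6 contrasts, so chance stays open for both. Both also rest on camera's preset correlation, since 2 lists for TGSA against D-8 and 1 list for PF-201 passed with an estimated correlation. By exact permutation 0 of 32 passed, but a list alone cannot pass there, as the smallest possible p is 0.00794 before adjustment over the lists. The aryl hydrocarbon receptor targets with PF-201 had the smallest p of the splits in a permutation of the library labels (real p = 1.42e-06, next 1.78e-06, 1 split), which excludes chance for this list taken singly. The choice of this list among 32 was not adjusted for there. The exact permutation of list means cannot decide this. The list had the smallest p that 252 labelings allow (0.00794), and adjustment over 32 lists raised it to 0.0847. Chance therefore stays open.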
